A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

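DNase-seq was done on nuclei of 3 Saccharomyces cerevisiae strains, and 1 list of hypersensitive sites per strain was used. Per the labels' protocols, cells were grown in rich medium with glucose to the same optical density, and nuclei were treated with a series of DNase I levels; which level was sequenced is not given in the sources used here. Bowtie 0.12.7 and the sacCer3 build are named in the submitters' processing notes. The peak caller and its threshold are not given in the sources used here. Each list is a headerless table of position, name and score, deposited by the authors, 1 list per sample. The score that the authors deposited has no stated scale; it was used only to rank or filter sites within a list. Across sites it rose with width (Spearman's rho 0.906 in wild type), so a high score also marks a wide site. Read depth is unknown, which limits how far fewer or weaker sites in a list can be read as closed chromatin.

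Groups were taken from the genotype given for each sample. Positions are given 1-based. The gene table used was that of assembly R64, taken as the same sequence as sacCer3, with 6477 genes; strand was read from the systematic names, and 6002 protein-coding genes with a start codon window were used. Chromosome lengths were taken as the largest gene or site end. Of 988 names in the 23 gene lists, 986 matched.

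Sites were called shared at an overlap of at least 1 bp. Chance overlap came from 1000 circular shifts along each chromosome. The expected number of joint losses was computed within 20 bins of wild-type score. A promoter was the 500 bp upstream of the start codon. For the location of sites, a midpoint was counted in a promoter window only where it lay outside coding sequence. The share of a list's genes that lost the promoter site was set beside 10000 random lists of the same size, matched in 3 classes of wild-type score, and coding coverage beside random lists matched in 3 classes of coding length. These ranges describe these libraries. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, and a share of 0 is given with the limit of 3 counts. No test between strains was run. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

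The code was tested on simulated data made from the 3260 wild-type sites: 976 of 976 planted losses and 200 of 200 planted gains were found, and the score-matched joint loss ratio averaged 1.00 with no joint effect, against 1.34 for the unmatched one.

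The gene lists, overlap rule, window, alternatives and the rule for named genes were fixed before the data were examined. Named were SBA1, GCN5, HSP82 and HSC82, then the highest-scored promoter sites lost in both strains (10), in each alone (6), gained in both and in each alone (5), and up to 4 members of each list outside the random range by promoter loss; a gene that this rule names is not reported here. The coding coverage comparison, its named members (up to 4 per list, those with the largest rise) and the setting of every site to 250 bp around its midpoint were chosen after seeing the data. Alternatives covered the overlap rule, stricter and equal-sized lists, merging within 150 bp, leaving out mitochondrial, ribosomal DNA and subtelomeric sites (25 kb), windows of 250 and 1000 bp, site midpoints, unmatched random lists and random placement in intergenic space. Promoter motifs were planned and not analysed here, because no genome sequence was used.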

Results

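DNase-seq maps open chromatin by sequencing the ends that DNase I cuts in nuclei, and stretches with many cuts are listed as hypersensitive sites. The series holds 3 libraries from the budding yeast strain BY4741, 1 each from the wild type, a deletion of SBA1 and a deletion of GCN5. SBA1 encodes the yeast form of p23, a co-chaperone of Hsp90, and GCN5 encodes the histone acetyltransferase of the SAGA complex. The series title gives the purpose as the joint effect of both proteins on open chromatin. With 1 library per strain there was no replicate check on any difference, so no test between strains was run and no p-value is given. Sequencing depth is unknown from the lists, and the intervals below are exact binomial 95% intervals that cover counting over sites only. Positions are on the sacCer3 build, and the score of a site is the authors' own value, used only within a list.

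The deleted genes were looked at first. GCN5 (YGR252W, chromosome VII 996869 to 998188) had no site in its coding sequence in the gcn5 deletion library, but none in wild type either, so this checks little. A site at chromosome VII 996505 to 996846, upstream of GCN5, was listed in the gcn5 deletion with a score of 3.95, above 91.8% of that list, and had no counterpart in wild type or the sba1 deletion. The sba1 deletion had 2 sites within GCN5 that covered 29.4% of it. SBA1 (YKL117W, chromosome XI 220324 to 220974) had a promoter site in all 3 lists. In the sba1 deletion that site reached 12 bp into the coding sequence, 1.84% of the gene, and the rest of the gene held no site. Neither gene's coding sequence carried a wild-type site, so the lists neither contradict the strain labels nor establish them. HSP82 and HSC82, which encode Hsp90, had no promoter or coding site in any list.

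Fewer but wider sites were listed in the sba1 deletion. It had 2439 sites against 3260 in wild type, a change of -25.2%, and the gcn5 deletion had 3062, a change of -6.07%. The median width of nuclear sites was 247 bp in wild type, 350 bp in the sba1 deletion and 261 bp in the gcn5 deletion. Sites over 1 kb made up 7.06%, 18.8% and 8.00% of the lists. Nuclear sites covered 1217 kb, 1557 kb and 1251 kb. The higher median in the sba1 deletion does not show that shared sites widened. Wild-type sites found again there already had a median width of 371 bp in wild type. Where 1 site overlapped just 1 site of the other list, the median ratio of sba1 deletion to wild-type width was 0.903. Each list also had 1 site spanning the mitochondrial chromosome from 1 to 85779, which says nothing of local openness. The highest-scored wild-type site lay in the ribosomal DNA at chromosome XII 459479 to 460917.

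In the sba1 deletion, 1742 of 3260 wild-type sites, or 53.4% (51.7 to 55.2), were found again, and 1518 were lost. The gcn5 deletion held 2587 of them, or 79.4% (77.9 to 80.7), and 673 were lost. Lists shifted along the chromosomes 1000 times overlapped 19.5% and 18.8% of wild-type sites on average. Of the sba1 deletion's sites, 869 or 35.6% (33.7 to 37.6) had no wild-type counterpart, and of the gcn5 deletion's sites 561 or 18.3% (17.0 to 19.7) had none. By shared bases the Jaccard index was 0.370 for wild type with the sba1 deletion, 0.664 for wild type with the gcn5 deletion and 0.459 between the deletion strains.

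Loss followed the wild-type score. Among the 10% of wild-type sites with the lowest scores, 21.8% were found in the sba1 deletion and 42.6% in the gcn5 deletion, while among the highest-scored 10% all 326 were found in both. Sites lost in the sba1 deletion had a median width of 173 bp and a median score of 2.05, against 371 bp and 2.46 for sites kept. Sites lost in the gcn5 deletion had a median width of 132 bp. Sharing depended strongly on the overlap asked for: when 50% of both sites had to overlap, 25.2% of wild-type sites were shared with the sba1 deletion and 59.8% with the gcn5 deletion.

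**Figure D1:**
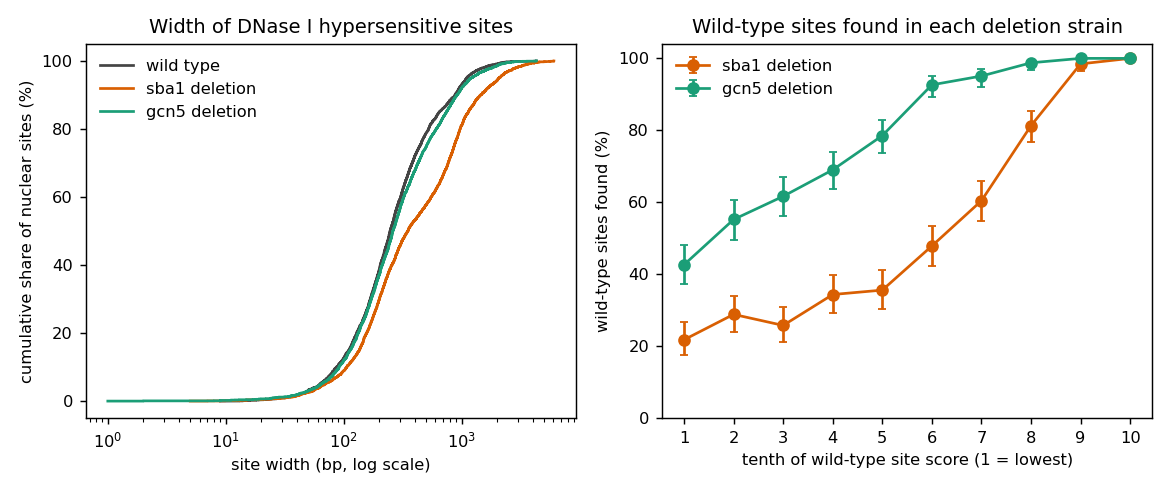
Left, cumulative share of nuclear sites by width in bp on a log axis for the 3 libraries. Right, percentage of wild-type sites found in each deletion strain by score bin from 1 (lowest) to 10 (highest), with exact binomial 95% intervals as bars; the sba1 deletion line rises from 21.8% to 100% and lies below the gcn5 deletion line until the last bin.

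Of the highest-scored wild-type promoter sites lost in the sba1 deletion only, PRP22, a splicing helicase, lost a site at chromosome V 178535 to 179014 with a wild-type score of 2.79. NOP12, which acts in ribosomal RNA maturation, lost a site at chromosome XV 252447 to 252993 with a score of 2.76. PET111, needed for translation of a mitochondrial messenger RNA, lost one at chromosome XIII 781836 to 782292. The shared promoter of IRC20 and RCK2, SFI1 and the splicing factor PRP46 followed. The SFI1 site was centred in coding sequence. Those lost in the gcn5 deletion only were lower-scored after the first. They overlapped the promoter windows of DFP3, PAL1, the replicative helicase subunit MCM7, BTN2, AVT7 and ACF4. The sites at DFP3, BTN2 and ACF4 were centred in coding sequence. At PAL1 another promoter site was listed in the gcn5 deletion, and DFP3 and ACF4 had no promoter site in the sba1 deletion either, since there the overlapping site lay outside the window.

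The highest-scored promoter sites gained in the sba1 deletion alone were 866 to 1764 bp wide, while the median of all 869 gained sites was 284 bp, below the 350 bp of the whole list. These highest-scored sites overlapped the promoter window of PDA1, a subunit of pyruvate dehydrogenase, at chromosome V 545954 to 547535 with a score of 3.61. The others overlapped the windows of SBH2 and GPA2, SLZ1, RDS3, and CDC27 and ALG3. All of these but the PDA1 site were centred in coding sequence, and the site at CDC27 and ALG3 covered 100% of the ALG3 coding sequence. RDS3 had another promoter site in wild type and in the gcn5 deletion. All 561 sites gained in the gcn5 deletion had a median width of 140 bp. The highest-scored promoter sites gained in the gcn5 deletion alone came, after the site at GCN5 itself, at TRS23 and TRS33, subunits of the TRAPP trafficking complex. The kinetochore gene CTF13 and the vacuolar aminopeptidase gene APE3 also had one. The TRS33 site was centred in coding sequence. The TRS23 site, at chromosome IV 954020 to 954268, had a score of 2.86.

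The location of sites differed in opposite directions. Site midpoints lay in coding sequence for 35.9% (34.3 to 37.6) of wild-type sites, 44.5% (42.5 to 46.5) of sba1 deletion sites and 32.3% (30.7 to 34.0) of gcn5 deletion sites. They lay within 500 bp upstream of a start codon and outside coding sequence for 43.7%, 36.9% and 47.3%, so the coding and promoter shares exclude each other. Of sites gained in the sba1 deletion, 68.0% (64.8 to 71.1) were centred in coding sequence, against 39.6% (35.5 to 43.8) of those gained in the gcn5 deletion. Coding sequence makes up 72.9% of the nuclear span, so all of these coding shares lay below that of evenly spread midpoints. The gained sites of the sba1 deletion came nearest to it. Genes for transfer RNA changed little in number: 121 of 275 had a site in wild type and 120 in each deletion strain.

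Among 6002 protein-coding genes, 2595 had a promoter site in wild type, 2320 in the sba1 deletion and 2637 in the gcn5 deletion. In the sba1 deletion 947 genes lost it, 36.5% of those with one, and 672 gained one. In the gcn5 deletion 363 lost it, or 14.0%, and 405 gained one. The lower count in the sba1 deletion depended on the setting. With equal numbers of best-scored sites the counts were 2180, 2320 and 2322, which turned its direction. At equal numbers, sites centred in promoter windows still made up 36.9% in the sba1 deletion and 45.4% in wild type. With site midpoints required in the window the gene counts were 1910, 1281 and 1935. With every site set to 250 bp they were 2325, 1655 and 2320.

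Gene groups differed in how often a gene with a wild-type promoter site had none in the sba1 deletion. Of the 947 such genes, 57 still had an sba1 deletion site on the wild-type site, which then lay outside the window. Ribosome biogenesis genes lost it at 16 of 24, or 66.7%, where the central 95% of random lists of similar wild-type score reached 58.3%. NOP12 lost its site, UTP20 had one only outside the window, and NOP1 and UTP6 kept theirs. Secretion and Golgi genes lost it at 18 of 30, or 60.0%, with an upper bound of 56.7%; MNN10 lost its site, ERP2 had one only outside the window, and ANP1 and COG5 kept theirs. Proteasome genes lost it at 11 of 17, which was at the bound and not beyond it. These lists are not fully independent, since genes were drawn singly for the random lists although 2 genes can share a site. NOP14 (ribosome biogenesis) and RPN5 (proteasome) had the same wild-type score of 1.97, and MAK21 and UBC5 of these lists both had 2.53. The secretion value fell inside the random range in 4 of 7 alternatives, at windows of 250 bp (66.7%) and 1000 bp (50.0%), with site midpoints (69.6%) and with every site set to 250 bp (73.1%). The ribosome biogenesis value did so in 2, with the better-scored 50% of each list (61.5%) and at 1000 bp (56.0%).

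Other groups kept their promoter sites more often than random lists. Cytosolic ribosomal protein genes lost 17 of 99, or 17.2%, with a lower bound of 26.3%; RPL2A and RPS1B kept theirs, RPL7B lost its site, and RPS14B had one only outside the window. This list, fixed by name pattern, also took in RPP1, a subunit of RNase P. Amino acid biosynthesis genes lost 3 of 28, among them PRO1, while HOM2 and TRP1 kept theirs. General stress genes lost 1 of 18, at ALD3, while GPD1 and TSL1 kept theirs. Glycolysis and fermentation genes lost 0 of 12, which allows a share of up to 25%, with ADH1 and GLK1 among those kept. Whether these last 3 groups lay below the random range depended on the setting. With every site set to 250 bp around its midpoint, losses were 41.7%, 53.8% and 40.0%, all inside the random range. That alternative was chosen after seeing the data. With equal numbers of best-scored sites the shares stayed low, at 8.70%, 6.25% and 0%, but lay inside the random range of that setting. With the better-scored 50% of each list, the first and the last were 33.3% and also inside.

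In the gcn5 deletion only the ribosomal protein list stood outside, with 4 of 99 promoter sites lost, or 4.04%, against a lower bound of 7.07%. RPS27A and RPS25B were among the 4. With every site set to 250 bp no list stood outside in this strain. Over both strains 7 of 46 values lay outside the central 95%, where 2.3 would by chance, and these ranges describe the libraries, not the strains.

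**Figure D2:**
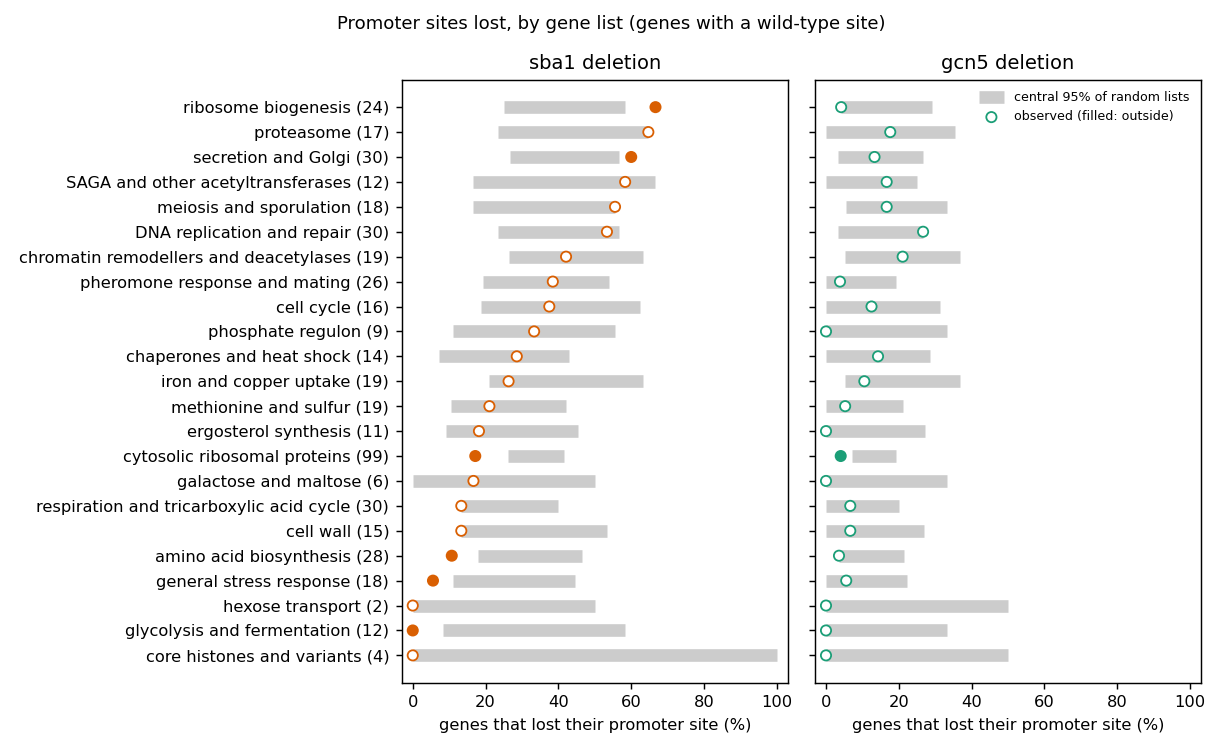
Percentage of genes with a wild-type promoter site that lacked one in the sba1 deletion (left) and the gcn5 deletion (right), for 23 gene lists, with the number of genes in brackets. Grey bars are the central 95% of 10000 random lists matched on wild-type score; filled points lie outside, 6 on the left and 1 on the right.

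Most sites lost in the gcn5 deletion were lost in the sba1 deletion too. Of the 673, 602 or 89.5% were absent from both, 71 from the gcn5 deletion only and 916 from the sba1 deletion only. Independent loss at the same overall rates would give 313 shared losses, and independent loss among sites of similar score 475, with a central 95% of 440 to 510, so the observed number was 1.27 times the score-matched value. When 50% of both sites had to overlap, the ratio was 1.06. The highest-scored promoter sites lost in both began with that of CHS5, which acts in export of chitin synthase, at chromosome XII 787529 to 787894 with a score of 2.55. Next came TGL1, UTP14, a factor of small ribosomal subunit assembly, SPC97, MUB1, and the shared promoter of SMA2 and the origin recognition gene ORC1. CUE2, CCM1, the SAGA subunit gene HFI1, and the shared promoter of MET32, a regulator of sulfur metabolism, and CHL4 followed. The sites at CHS5 and SPC97 were centred in coding sequence.

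Of the 869 sites gained in the sba1 deletion, 182 overlapped a site gained in the gcn5 deletion, where shifted lists gave 27.8 on average and a central 95% of 18 to 38. The shifts ran over all space outside wild-type sites and took no account of location. Of the sites gained in the gcn5 deletion, 46.2% were centred in promoter windows, so this baseline may be too low. Random placement in intergenic space was not run for gained sites. The best-ranked overlapped the promoter windows of MYO3, the cell wall gene SED1 (chromosome IV 599803 to 600652), FOL2 with HUA1 and YTA7, HPF1, and BAP3 with HEM12. The sba1 deletion sites at MYO3, FOL2 with HUA1 and YTA7, and HPF1 were centred in coding sequence. MYO3 had a promoter site in wild type as well. Both the shared losses and the shared gains rest on the same wild-type list, so a site wrongly present or missing there counts in both strains.

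Sites in the sba1 deletion reached far into coding sequence, a comparison chosen after the wider sites had been seen. Coding bases under sites came to 465 kb in wild type, 832 kb in the sba1 deletion and 459 kb in the gcn5 deletion, while noncoding bases came to 752, 725 and 792 kb. Genes with at least 50% of their coding sequence covered numbered 328, 719 and 363. The sba1 deletion had fewer sites centred in coding sequence, 1085 against 1170 in wild type, so its excess of coding bases did not come from their number. With every site set to 250 bp its coding bases were 0.906 times those of wild type in place of 1.79 times.

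The wider coverage was uneven among gene groups. Mean coverage of glycolysis and fermentation genes was 11.7% in wild type, 50.1% in the sba1 deletion and 17.7% in the gcn5 deletion, and 19 of 22 members were higher in the sba1 deletion. ADH1 was covered at 16.0% and 100%, PDC1 at 17.7% and 98.5%, CDC19 at 6.99% and 83.3%, and ADH2, which glucose represses, at 0% and 81.2%. Cell wall genes went from 3.66% to 27.2%, with KRE1, SPI1 and TIP1 from 0% to 100%. Methionine and sulfur genes went from 8.70% to 28.8%, with CYS3 from 4.73% to 100%. General stress genes went from 16.0% to 30.5%, at the edge of the random range, with TFS1 from 0% to 100% and HSP12 from 0% to 50.9%. Amino acid biosynthesis genes went from 5.67% to 19.1%, with THR1 from 0% to 94.6%.

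Ribosomal protein genes stood on the other side, at 16.7% in wild type and 15.8% in the sba1 deletion. Ribosome biogenesis genes at 5.70% and 5.34% and pheromone response genes at 7.17% and 5.45% did so only at the edge of the random range. Their differences were -0.365 points against a lower bound of -0.0844, and -1.72 points against -1.24. Random lists of similar coding length were mostly higher in the sba1 deletion. In the gcn5 deletion the glycolysis list was above the random range and the secretion list, at 5.68% and 3.68%, below it. Over both strains 10 of 46 values lay outside, where 2.3 would by chance.

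**Figure D3:**
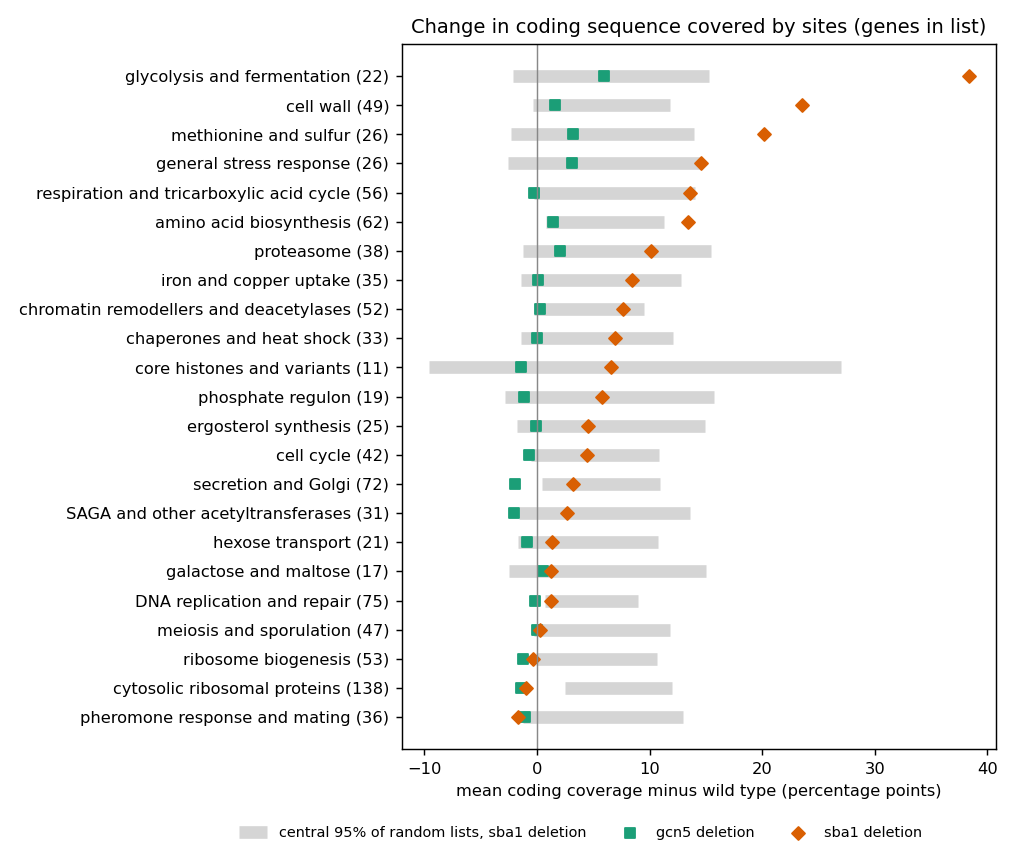
Mean share of coding sequence covered by sites, as the difference from wild type in percentage points, for 23 gene lists in the sba1 deletion (diamonds) and the gcn5 deletion (squares), with the number of genes in brackets. Grey bars are the central 95% of random lists for the sba1 deletion; glycolysis and fermentation lies farthest out at 38.4 points.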

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

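The results below stand out because the sba1 deletion and the gcn5 deletion differed from wild type in opposite directions. With 1 library each the difference was not tested. The tests of calling threshold and of width over all shared sites were chosen after the result was seen.

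The share of site midpoints in coding sequence was 8.60 percentage points higher in the sba1 deletion than in wild type and fell by 3.59 in the gcn5 deletion. The share in promoter windows outside coding sequence fell by 6.85 points in the sba1 deletion and was 3.61 points higher in the gcn5 deletion. No site counted in both classes, so these shares are not independent of each other. Coding bases under sites were 367 kb higher in the sba1 deletion and fell by 5.87 kb in the gcn5 deletion, the latter a difference whose sign turned in stricter lists. Noncoding bases fell by 27.0 kb in the sba1 deletion and were 40.1 kb higher in the gcn5 deletion. The number of genes with a promoter site fell by 275 and was 42 higher, but with equal numbers of best-scored sites it was 2180 in wild type, 2320 in the sba1 deletion and 2322 in the gcn5 deletion, so these directions were no longer opposite. For ribosomal protein genes it fell by 5 and was 12 higher, and for ribosome biogenesis genes it fell by 12 and was 3 higher. Mean coding coverage of secretion and Golgi genes was 3.21 points higher in the sba1 deletion, inside its random range of 0.419 to 10.9, and fell by 1.99 in the gcn5 deletion, just below its lower bound of -1.86. The means were opposite but most changed members were not: coverage was higher for 13 and lower for 24 in the sba1 deletion, and higher for 6 and lower for 24 in the gcn5 deletion.

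The wide coding coverage in the sba1 deletion is the pattern most in need of a second library. A lower threshold or greater depth that only added sites would remove none, yet 22.4% (20.4 to 24.5) of the better-scored 50% of wild-type sites were absent. With wild-type sites in 10 score bins, 47.9% were found in bin 6, 60.4% in bin 7 and 81.3% in bin 8, against 98.5% in bin 9 and 100% in bin 10. Because caller, threshold and depth are unknown, this test cannot decide on a change that also drops lower-scored sites. Uniform widening was tested first, before its result was seen, at ribosomal protein promoters: the median width ratio there was 1.02, inside the random range of 0.719 to 1.07, which is the outcome uniform widening predicted. That test was a poor one, because the median over all 1303 one-to-one sites was 0.903, so there was no widening there to spread evenly. Over all shared wild-type sites, 55.3% (52.9 to 57.7) were narrower than the widest sba1 deletion site on them, too few for every site to have widened. A difference in depth or calling that also drops sites, a difference in DNase I digestion between nuclei preparations, and the SBA1 deletion itself stay open and untested.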

How the results depend on the processing

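The setting of every site to 250 bp around its midpoint, and every value for coding bases, were chosen after seeing the data; the other alternatives were planned. Of 180 values under alternatives, 55 moved beyond their limits, 18 list values no longer lay outside the random range, 3 reversed and the others stayed within their limits. In every setting fewer wild-type sites were shared with the sba1 deletion than with the gcn5 deletion, and joint loss exceeded its score-matched expectation. The ribosomal protein list lost fewer promoter sites in the sba1 deletion than random lists in each setting run. Unknown depth limits all counts. Where no cause is named below, the cause was not tested. Promoter motifs were not run, and no paired analysis was possible because each strain has 1 library.

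With an overlap of 50% of both sites, sharing was 25.2% for the sba1 deletion and 59.8% for the gcn5 deletion, gained sites were 66.3% and 36.3%, joint losses numbered 1249 at a ratio of 1.06, and sba1 deletion sites were found in the gcn5 deletion more often than in wild type by 7.67 points. The lower sharing follows from the stricter rule; the cause of the lower ratio and the larger difference was not tested. With sites within 200 bp counted as shared, 16.6% of gcn5 deletion sites were gained, and with sites within 150 bp merged, 33.0% of sba1 deletion sites were.

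With the better-scored 50% of each list, sharing with the sba1 deletion was 49.0%, gained sites 40.7%, joint losses 317, joint gains 106 and the difference in overlap 6.89 points. Midpoints in coding sequence made up 28.8% in wild type and 26.3% in the gcn5 deletion, and in promoter windows 46.0% and 50.3%. Genes with a promoter site numbered 1646 and 1700. In the sba1 deletion 3 lists lay outside the random range, and ribosome biogenesis (61.5% lost), glycolysis (33.3%) and amino acid biosynthesis (33.3%) no longer did. Coding bases in the gcn5 deletion were 1.04 times wild type, a reversal.

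With equal numbers of best-scored sites, sharing was 62.8% and 81.5%, gained sites 41.1% and 20.4%, and joint losses 381. Genes with a promoter site numbered 2180 in wild type, 2320 in the sba1 deletion and 2322 in the gcn5 deletion, so the sba1 deletion was above wild type and not below. Midpoints in coding sequence made up 32.7% in wild type and 29.6% in the gcn5 deletion. Glycolysis (0% lost), general stress (6.25%) and amino acid biosynthesis (8.70%) fell inside the random range, and coding bases in the gcn5 deletion were 1.01 times wild type, a reversal. With the better-scored 50% of the sites asked about against full lists, sharing was 77.6% and 97.3%, gained sites 27.0% and 3.72%, joint losses 36 at a ratio of 1.83, joint gains 20 and the difference in overlap 8.78 points.

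With a promoter window of 250 bp, secretion (66.7% lost) and general stress (6.67%) fell inside the random range, 3 lists lay outside in the gcn5 deletion, and midpoints in the window made up 31.2% in wild type, 24.0% in the sba1 deletion and 32.3% in the gcn5 deletion. With 1000 bp, ribosome biogenesis (56.0%) and secretion (50.0%) fell inside, and the shares were 52.2%, 45.3% and 56.3%. With site midpoints in the window, 1281 genes had a promoter site in the sba1 deletion, 1910 in wild type and 1935 in the gcn5 deletion, 2 lists lay outside in it and 3 in the gcn5 deletion, and secretion (69.6%), glycolysis (57.1%), general stress (40.0%) and amino acid biosynthesis (43.8%) fell inside.

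Setting every site to 250 bp widened narrow sites too, 50.6% of the wild-type list and 39.1% of the sba1 deletion list. Genes with a promoter site then numbered 2325 in wild type, 1655 in the sba1 deletion and 2320 in the gcn5 deletion, and sharing was 40.9% and 74.4%, gained sites 45.5% and 21.2%, and the joint loss ratio 1.16. In the sba1 deletion 2 lists lay outside and in the gcn5 deletion 0, and secretion (73.1%), glycolysis (40.0%), general stress (53.8%) and amino acid biosynthesis (41.7%) fell inside. Coding bases in the sba1 deletion were 0.906 times wild type, a reversal that mixes width removed from wide sites with width added to narrow ones. With random placement in intergenic space, chance sharing was 27.1% with the sba1 deletion and 28.4% with the gcn5 deletion, still below the observed values.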

Other observations

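In the next paragraph, the gene list and the bound were written before its values were seen, but the idea came from genes already seen, such as ADH2, SPI1 and HSP12. Of the tests after it, the comparison of private sites was written before its result was seen, and the tests of joint loss by score and of the gene lists by score were chosen after.

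Genes repressed by glucose were more widely covered in the sba1 deletion. Over 30 such genes outside the other lists, mean coding coverage was 9.39% in wild type, 25.9% in the sba1 deletion and 10.9% in the gcn5 deletion. Coverage was higher in the sba1 deletion for 16 genes and lower for 6. GUT1, a glycerol kinase, went from 0% to 96.2%, ACS1, an acetyl-CoA synthetase, from 0% to 90.5%, and ALD4, an aldehyde dehydrogenase, from 6.28% to 76.5%, while CYB2 went from 13.3% to 1.35%; these 4 were chosen after their values were seen. The mean rise of 16.5 points lay above the random range of -1.10 to 11.6. A candidate explanation is a culture nearer to glucose depletion at harvest. The rise was not particular to glucose-repressed genes, as the glycolysis and fermentation list, which includes ADH2, rose by 38.4 points. Respiration genes rose by 13.6 points, inside their random range but near its upper bound of 14.1. Galactose and maltose genes rose by 1.28 points, well inside theirs. The labels give the same optical density at harvest for all strains. An effect of the SBA1 deletion on glucose-repressed genes would look alike, so strain and culture are confounded here.

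Sites lost in both deletion strains numbered 602, above the 440 to 510 that independent misses at the same rate within each score bin would give. The excess was small when 50% of both sites had to overlap, at a ratio of 1.06. Sites within a bin may differ in other traits that make them hard to list, which these draws cannot exclude. Sites lost in both were centred in coding sequence at 50.5%, against 35.9% of all wild-type sites. This comparison was not matched on score: their median score was 1.98, against 2.19 for all nuclear wild-type sites. In the better-scored 50% of the wild-type list the coding share was 28.8%, so it differed with score. Chance peaks of the wild-type library might also account for the sites lost in both, since such peaks would be absent from both other lists. If so, private sites should be in excess in each list. The sba1 deletion had 682 private sites against 331 expected, 2.06 times, and the gcn5 deletion 271 against 349, 0.777 times, so 1 of the 2 deletion lists showed the excess and chance peaks of the wild-type library cannot be told apart from a joint effect of the deletions. The excess in wild type was thus not the largest of the 3, and a replicate wild-type library would decide.

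For the promoter sites lost in the sba1 deletion, low wild-type scores were weighed for 3 gene lists. With lists matched in 3 score classes, 2 of the 3 lists stayed above the random range, which met neither bound set for the low wild-type scores explanation. With finer matching in 10 classes, ribosome biogenesis (16 lost, bound 15) and secretion (18 lost, bound 17) made 2 of 2 above, each by 1 gene; these lists were picked because they had passed the coarser match. With the better-scored 50% of each list, secretion lost 13 of 17 (76.5%) and stayed above the random range, while ribosome biogenesis lost 8 of 13 (61.5%) and lay inside it. With equal numbers of best-scored sites both lists stayed above the random range, ribosome biogenesis at 13 of 20 (65.0%) and secretion at 15 of 26 (57.7%). Low wild-type scores thus stay open for both lists, since each passed the finer match by only 1 gene. The ribosome biogenesis value lay inside the random range in 2 of 7 alternatives and the secretion value in 4. For secretion these were windows of 250 bp (66.7% lost) and 1000 bp (50.0%), site midpoints (69.6%) and every site set to 250 bp (73.1%), against 60.0% in the main setting. The proteasome list, with 11 lost at a bound of 11, was no higher than low wild-type scores allow. The effect of the SBA1 deletion stays open as untested.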
